A study of Mus musculus with 18 samples.

How the data were processed

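Gene expression had been measured by the authors in mouse heart, as total RNA on Affymetrix U74Av2 oligonucleotide arrays, with 1 array per sample per the labels. The labels name the mice as FVB or as TNF transgenic, and describe the transgene, tumour necrosis factor alpha, as cardiac-specific. Groups, sexes and ages were taken from the sample titles: FVB females and males of 3 weeks, TNF transgenic females and males of 3 weeks, transgenic males of 13 weeks and transgenic females of 40 weeks. The table holds 18 columns in 6 groups. FVB female replicates 1 and 2 hold identical values in every probe set, so they differed by less than any sampling noise and were counted as 1 sample. This leaves 17 distinct arrays, 2 of them FVB females and 3 in each other group. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. No hybridisation date, scan date or batch was used here, since the labels give none.

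The deposited values are a probe set intensity (signal) on a linear scale, with 1 decimal and no value below 0, scaled by the authors to a common level. The mean between the 2nd and 98th percentiles was 499.9 on the lowest array and 500.4 on the highest, a ratio of 1.001. The software, background method and scaling settings behind the values are not given in the sources used here. Under a rule set before the data were examined, arrays whose trimmed means lay within 1.2 times of each other were used as deposited, without further scaling. That rule, the groups, the tests, the gene lists, the naming of genes and the alternatives not said to be added were all fixed before the data were examined. The design had counted on 18 distinct arrays, and the identical columns are the only change made to it.

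Signals below the 25th percentile of all pooled values, 44.675, were set to that floor, and values were then taken as log2. Leaving out 66 control probe sets, 12422 remained. The 60% of these with the highest mean log2 signal, 7453 probe sets, were tested. Values at the floor have no order, and a fold against a group that lies wholly at the floor is given as "at least". Where only some arrays of the lower group lie at the floor, the log2 difference is a lower limit of its size, for every such gene named. Symbols came from the platform annotation given with the table, which can be old. In it 10833 probe sets had 1 gene symbol, 396 had several and 1193 had none. Of the probe sets with 1 symbol, 10817 carry a symbol that a current RefSeq gene table also holds, and no symbol was replaced. Probe sets with several symbols or none were tested but not named. The tested probe sets with 1 symbol numbered 6752 and covered 5700 genes. A gene is represented by its probe set with the highest mean over all arrays, and the text says where another probe set of a named gene was called in the opposite direction. Genome coordinates were not used here.

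Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with a mean for each of the 6 groups in a single fit of the 17 arrays, which left 11 residual degrees of freedom and 4.89 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 7453 probe sets within a comparison, called at 0.05. All log2 differences and SEs below come from this fit. The transgene effect at 3 weeks is the mean of the female and the male difference, with equal weight. The sex difference of that effect, and the difference between the 2 age changes, were tested as contrasts of their own. Among 33 gene lists, the 30 with at least 4 measured genes were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. The lists for lung, for liver and plasma proteins and for sex-linked genes had 1, 1 and 2 measured genes and were not tested. Camera with an estimated correlation and fry were run beside it. Counts of called genes are over all probe sets tested, and where they differ the count adjusted over the list alone stands beside them.

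Genes are named by rule. For the effect at 3 weeks and for the 2 age changes, the named genes are the 10 highest and 10 lowest called log2 differences whose groups of arrays do not overlap, up to 4 genes of smallest p in each list, and a fixed set that was always looked up. For the other comparisons they are the 5 highest, the 5 lowest and the sex-linked genes. Genes outside the rule are marked as chosen after their values were seen.

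The alternatives tried were quantile normalisation, a common median, a floor at the 40th percentile, log2 of signal plus 50, no filter, the brightest 40% of probe sets, an intensity trend with robust variance, array weights, fitting only the groups compared, the replicate number as a block, the mean over a gene's probe sets, and leaving out each array. Keeping both identical columns, and leaving out doubted FVB arrays, were added after seeing the data. The fit was also tested on simulated data of 7453 probe sets, in which 100 carried a log2 difference of 1 and another 100 a difference of 2. That is a far smaller share than the 46.6% called at 3 weeks. Noise was drawn independently for each probe set with the same SD on all arrays. The simulations thus had no correlated genes and no outlying array, and their rates need not hold for these data. At a log2 difference of 1, the share recovered was 79% at 3 weeks, 59% for 13 weeks and 67% for 40 weeks. At a difference of 2 it was 96%, 92% and 92%. The simulations as a whole gave 11, 9 and 11 false calls. Figures were drawn in Python 3.11.15. Arrays carry no counting depth, and the number of arrays limits the precision.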

Results

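The series compared hearts of FVB mice with hearts of mice carrying a cardiac-specific TNF-alpha transgene, and followed the transgenic hearts to later ages, in order to describe expression in compensated hypertrophy and in dilated failure per the labels. There were 5 distinct FVB arrays of 3 weeks (2 female, 3 male), 6 transgenic arrays of 3 weeks (3 female, 3 male), 3 transgenic male arrays of 13 weeks and 3 transgenic female arrays of 40 weeks. All FVB samples were 3 weeks old, and the 2 later ages are of different sexes. The first principal component held 51.0% of the variance and placed all 5 FVB arrays on one side and all 12 transgenic arrays on the other.

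**Figure D1:**
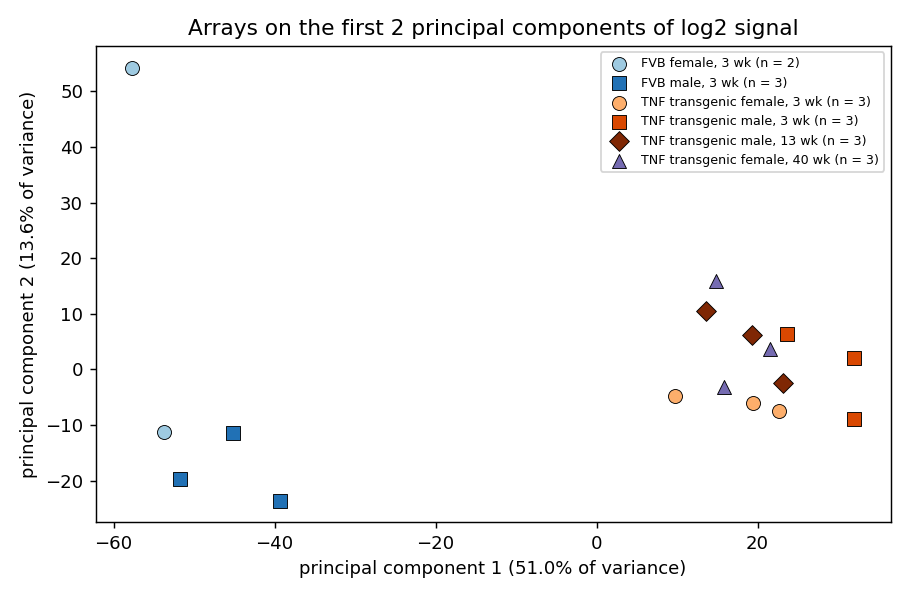
The 17 distinct arrays on the first 2 principal components of log2 signal of the tested probe sets (axes in arbitrary units, with 51.0% and 13.6% of the variance), coloured by group. The FVB arrays lie left of the transgenic arrays, and the array of FVB female replicates 1 and 2 lies apart on the second axis.

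The array of FVB female replicates 1 and 2 stood apart from all others. Its Spearman correlation with the other 16 arrays was 0.767 to 0.850, while the other 4 FVB arrays correlated at 0.953 to 0.962 among themselves and at 0.885 to 0.942 with the transgenic arrays. On it 7.35% of probe sets lay at the floor, and its 5th percentile signal was 37.9, against 4.1 to 8.9 on the other arrays of 3 weeks. The ratio of 3' to 5' Actb control signal, a sign of RNA integrity, was 1.71 ± 0.26 (SD, n = 5) in FVB and 1.26 ± 0.10 (SD, n = 6) in transgenic hearts of 3 weeks (exact permutation test, two-sided, p = 0.0043). The same ratio for Gapdh was 1.06 ± 0.08 (SD, n = 5) and 1.005 ± 0.09 (SD, n = 6), with an exact permutation p = 0.292. These 2 ratios, the 5th percentile signal (exact permutation p = 0.0152), the share at the floor (exact permutation p = 0.281) and the 18S control signal (exact permutation p = 0.866) made up a family of 5 comparisons, and the p-values are unadjusted.

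Xist, the transcript that silences an X chromosome in female cells, and the Y-linked genes Eif2s3y and Uty were compared with the sex in the labels. In the 6 transgenic female arrays, Xist signal was 1721 to 3934 and Eif2s3y at most 30.8. The 6 transgenic male arrays had Xist of at most 34.7 and Eif2s3y of 347.8 to 484.4. Of the arrays labelled FVB male, replicate 3 had Xist 5.9 and Eif2s3y 544.9, while replicate 2 had Xist 2706, Eif2s3y 67.4 and Uty 16.9. Replicate 1 had Xist 1381, Eif2s3y 298.7 and Uty 129.7. As labelled, Xist was called lower in transgenic than in FVB males (at least 12.3-fold lower, with all 3 transgenic male arrays of 3 weeks at the floor, limma adjusted p = 0.0089), which follows from those 2 arrays. Both arrays labelled FVB female had Xist (2075 and 1159) with Eif2s3y of 115.3 and 40.9. The sexes below are those of the labels, and sex comparisons that use FVB males rest on groups in which 2 of the 3 arrays carry Xist.

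**Figure D2:**
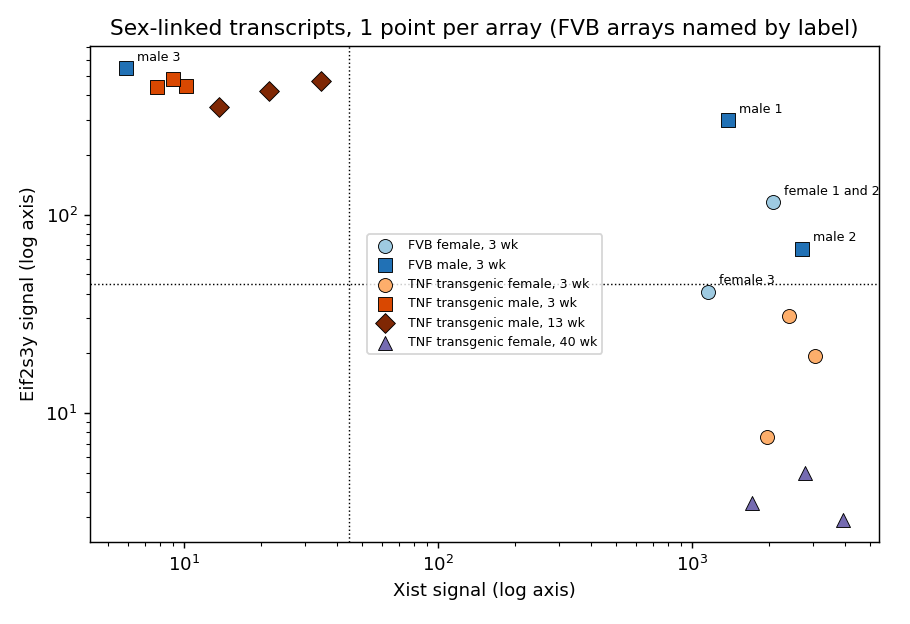
Signal of Xist against signal of Eif2s3y, both on log axes, with 1 point per array, shape and colour by labelled group, and dotted lines at the floor of 44.675. The arrays labelled FVB male 1 and FVB male 2 lie at Xist 1381 and 2706, far right of FVB male 3 at 5.9.

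At 3 weeks, transgenic hearts carried far more Tnf transcript than FVB hearts, with a mean signal of 9404 ± 2170 (SD, n = 6) against 43.9 ± 45.8 (SD, n = 5), where 4 of the 5 FVB arrays lay at the floor. With those arrays set to the floor the log2 difference was 7.31 (SE 0.24, limma adjusted p = 1.8e-12), which is a lower limit. Genes of macrophages and of leukocyte recruitment followed: Mmp12, the macrophage elastase, by 6.83 (SE 0.16), Ccl2, a monocyte-attracting chemokine, by 5.73 (SE 0.24), Lgals3, a lectin abundant in macrophages, by 5.52 (SE 0.14), and Mmp9, a gelatinase, by 5.50 (SE 0.23). These too are lower limits, since 2 to 4 of the 5 FVB arrays lay at the floor for each. Chil1, a chitinase-like protein, and Ccl5, a T cell chemokine, lay at the floor on all 5 FVB arrays and were at least 52.3-fold and at least 39.2-fold higher in transgenic hearts. On the other side, Ces1d, a carboxylesterase of lipid metabolism, fell by 3.82 (SE 0.31), Aqp1, a water channel of endothelium, fell by 3.31 (SE 0.28), and Gsn, the actin-severing gelsolin, fell by 2.28 (SE 0.16). Pdk4, a kinase that restrains glucose oxidation, fell by 2.10 (SE 0.28) and Slc27a1, a fatty acid transporter, fell by 2.21 (SE 0.29). Other genes among the 20 most changed were H2-Ab1 (log2 difference 5.55), Cxcl13 (5.23) and Cd52 (5.04), and on the lower side Adh1 (-2.54), Entpd5 (-2.26), Kcnd2 (-1.98), Penk (-1.94) and Plin4 (-1.89).

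Limma called 3474 of the 7453 probe sets (46.6%), 1843 higher and 1631 lower in transgenic hearts. Of the called probe sets, 1136 differed by at least 2-fold, 793 higher and 343 lower. Counted by the probe set that represents each gene, 2724 of 5700 genes were called. The balance of all calls turned with quantile normalisation (1750 higher, 1882 lower) and without the filter (1892 higher, 2042 lower). Leaving out the outlying FVB female array and the arrays labelled FVB male 1 and 2, an alternative added after seeing the data, gave 2655 calls, 1549 higher and 1106 lower. It leaves 1 FVB array of each sex, assumed to vary like the transgenic groups. The Actb ratio given above differed between the same groups.

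Lists of immune cells and signals rose in transgenic hearts. Counts and medians are of the genes that passed the filter, which favours genes high on the 12 transgenic arrays. On the array were 32 T and NK, 47 chemokine and cytokine, 31 B cell and 24 neutrophil and mast cell genes. Of these 17, 28, 20 and 9 were tested, so the shares that rose may be overstated. For macrophage markers 35 of 39 were tested. Of 35 measured macrophage markers, 30 rose, 2 fell (3 adjusted over the list alone) and 3 did not pass, with a median log2 difference of 2.65 (camera adjusted p = 6.2e-18). Examples are Cd53, a leukocyte tetraspanin (4.83), Clec4d, a C-type lectin receptor (4.43), and Itgax, an integrin of dendritic cells and macrophages (3.63). Of 28 chemokines and cytokines 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.91 (camera adjusted p = 2.9e-12), among them Ccl9 (4.43), the interferon-induced Cxcl9 (4.26) and the neutrophil attractant Cxcl5 (4.09). Class II antigen presentation had 13 of 14 genes higher (14 adjusted over the list alone), with a median of 2.34 (camera adjusted p = 1.2e-09), such as H2-Aa (4.79), the class II chaperone Cd74 (3.56) and the protease Ctss (3.96). In TNF and NF-kB signalling, a list that holds Tnf itself, 15 of 19 rose and 1 fell, with a median of 1.86 (camera adjusted p = 1.4e-08), with the adhesion molecules Icam1 (3.51) and Vcam1 (3.06) and the adaptor Traf1 (2.96). The interferon response (19 higher, 1 lower of 24, median 1.45, camera adjusted p = 2.3e-08) included the GTPases Ifi47 (3.64) and Igtp (3.43) and the transcription factor Irf8 (2.69). Class I presentation (12 higher, 2 lower of 14, median 1.73, camera adjusted p = 2.7e-06) included the immunoproteasome subunits Psmb9 (4.04) and Psmb8 (3.08). These 6 calls held with an estimated correlation, the weakest at adjusted p = 0.0494.

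T and NK markers (13 higher, 1 lower of 17, 14 and 2 adjusted over the list alone, median 1.74) were called at camera adjusted p = 9.8e-06, and adjusted p = 0.10 with an estimated correlation. Zap70, a kinase of T cell receptor signalling, rose by 2.73 and the cytokine receptor Il7r by 2.43. Complement and acute phase genes (13 higher, 4 lower of 20, median 1.36) were called at 0.0012, and at adjusted p = 0.103 with an estimated correlation, with properdin, Cfp, at 4.49 and haptoglobin, Hp, at 3.14. Other leukocyte lists were not called. B cell and immunoglobulin genes had 8 higher and 1 lower of 20 (median 0.30, camera adjusted p = 0.0551). Blnk, an adaptor of B cell receptor signalling, rose by 2.85 and the Ighm probe set of highest signal by 1.65. A second Ighm probe set, chosen after its values were seen, lay at the floor on all 6 transgenic arrays of 3 weeks. Over the 24 tested immunoglobulin probe sets the median was -0.17, with 5 higher and 4 lower. Neutrophil and mast cell markers had 5 higher and 3 lower of 9 (median 1.40, camera adjusted p = 0.114), and S100a8 rose by 2.33. Without the outlying FVB female array, a test of the lists added after seeing the data, both were called, B cell genes with a median of 0.62 (camera adjusted p = 0.0071) and neutrophil and mast cell markers with a median of 1.81 (camera adjusted p = 0.0167). With all arrays and an estimated correlation neither was called, at adjusted p = 0.292 and 0.436, while fry called both. With quantile normalisation, and with the removal of 3 FVB arrays, camera adjusted p was 0.0413 and 0.0136 for B cell genes and 0.107 and 0.021 for neutrophil and mast cell markers.

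Genes of energy metabolism fell. Fatty acid oxidation and uptake had 24 of 26 genes lower and 1 higher (25 and 1 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 5.2e-11, adjusted p = 0.0357 with an estimated correlation). Eci1 and Cpt2, of beta-oxidation and carnitine transfer, fell by 1.34 and fell by 1.29, and Mlycd, which degrades malonyl-CoA, fell by 1.33. In oxidative phosphorylation and the TCA cycle 52 of 53 genes fell (all 53 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 3.8e-17, but adjusted p = 0.103 with an estimated correlation). Cox8b, a cytochrome oxidase subunit of muscle, fell by 1.73, and Uqcrc1 and Ogdh fell by 1.15 and fell by 1.11. Glucose uptake and glycolysis had 13 lower and 5 higher of 21 (median -0.59, camera adjusted p = 0.0036, adjusted p = 0.214 with an estimated correlation), with the insulin-responsive transporter Slc2a4 at -1.69 and glycogen synthase, Gys1, at -1.35.

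Contractile and excitation genes moved in a similar direction. A lower share of cardiomyocytes could give such falls too, and cannot be told apart here. Of 18 sarcomere genes, a list that also holds muscle metabolic proteins, 15 fell and 1 rose (median -0.88, camera adjusted p = 8.1e-06, adjusted p = 0.144 with an estimated correlation), including the Z-disc protein Ldb3 (-1.37), myoglobin, Mb (-1.10), and Myh6, the adult alpha myosin heavy chain (-0.84). The size of this fall depended on scaling: with quantile normalisation the sarcomere median was -0.45, with 12 lower and 0 higher. Calcium handling and ion channels had 11 lower and 1 higher of 18 (median -0.69, camera adjusted p = 0.0011, adjusted p = 0.10 with an estimated correlation), with Hrc (-1.59), the ryanodine receptor Ryr2 (-1.17), the calcium channel Cacna1c (-1.13) and Atp2a2, the sarcoplasmic calcium pump (-0.99). The list of fetal and hypertrophy genes was not called as a group (8 higher, 5 lower of 20, camera adjusted p = 0.524). Within it the natriuretic peptide genes Nppa and Nppb rose by 1.80 (SE 0.33) and 0.95 (SE 0.20), Myh7, the beta myosin heavy chain, rose by 1.22 (SE 0.21) and skeletal actin, Acta1, by 0.81 (SE 0.29), while Csrp3 fell by 1.02.

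Cell cycle genes had 34 higher and 1 lower of 48 (35 and 1 adjusted over the list alone), with a median of 1.003 (camera adjusted p = 6.8e-08, adjusted p = 0.13 with an estimated correlation), such as the topoisomerase Top2a (2.07), the replication helicase subunit Mcm5 (1.69) and Cks2 (1.63). Matrix proteases and TGF-beta genes (11 higher, 2 lower of 20, 12 and 2 adjusted over the list alone, median 0.48, camera adjusted p = 0.0019, adjusted p = 0.0928 with an estimated correlation) held Timp1, a protease inhibitor, at 1.76. Collagen and matrix genes were mixed (14 higher, 8 lower of 37, median 0.24, camera adjusted p = 0.323): Col14a1 rose by 2.22 and Tnc by 1.64, Col1a1 rose by 0.54 (SE 0.19), and Col3a1 was at 0.31 (SE 0.24, adjusted p = 0.306). Without the outlying FVB female array the median of this list was 0.0099 (11 higher, 7 lower, camera adjusted p = 0.71). Immediate early genes (10 higher, 1 lower of 19, 10 and 2 adjusted over the list alone, median 0.55, camera adjusted p = 0.043, adjusted p = 0.195 with an estimated correlation) included Atf3 (2.62) and Egr2 (2.68). Cell death genes (15 higher, 4 lower of 27, 15 and 6 adjusted over the list alone, camera adjusted p = 0.0787) and oxidative stress genes (9 higher, 14 lower of 37, camera adjusted p = 0.172) were not called, although the inflammatory caspases Casp4 and Casp1 rose by 2.43 and 2.33, Hmox1 rose by 1.63 and Gpx3 fell by 1.39.

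Markers of other cells and tissues did not move together. Endothelial markers (3 higher, 6 lower of 21, median -0.19, camera adjusted p = 0.323), smooth muscle and pericyte markers (4 higher, 4 lower of 12, camera adjusted p = 0.524), atrial markers (1 higher of 8, camera adjusted p = 0.703), thymus genes (1 higher, 1 lower of 4, camera adjusted p = 0.792), skeletal muscle genes (5 lower of 9, camera adjusted p = 0.111) and circadian genes (2 higher, 7 lower of 13, camera adjusted p = 0.114) were not called. Adipocyte genes (1 higher, 4 lower of 9, 1 and 5 adjusted over the list alone, median -0.61) were called at camera adjusted p = 0.049, and at adjusted p = 0.103 with an estimated correlation, with Scd1 at -1.36. Erythroid genes (5 lower of 7, median -0.71) were called at 0.0179, and at adjusted p = 0.15 with an estimated correlation, with the globin gene Hba-a1 at -0.82. In all, camera called 18 of 30 lists, 11 up and 7 down, of which 7 held with an estimated correlation, and fry called 27. In every list camera called in any comparison, the median, the mean and the test had the same sign.

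**Figure D3:**
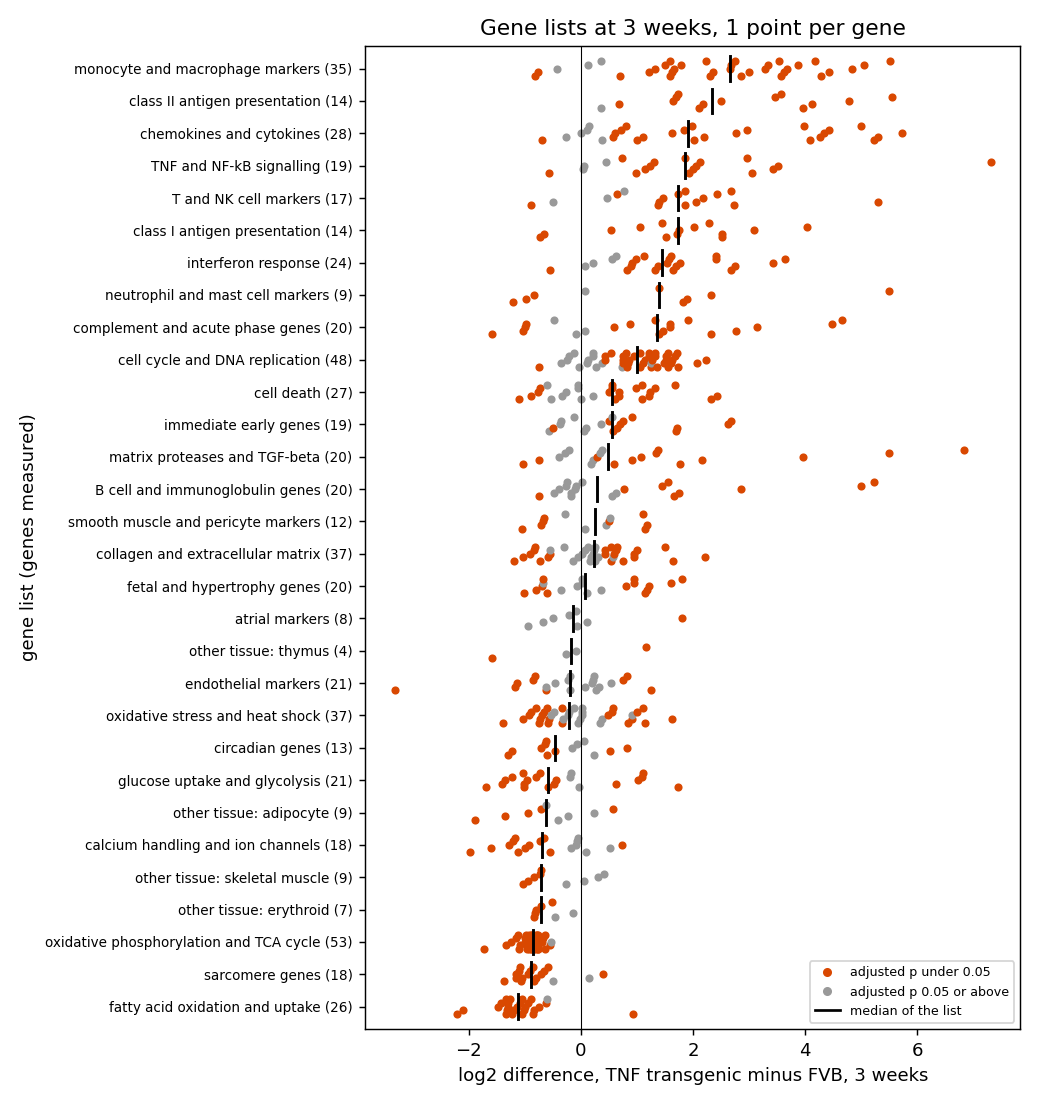
Log2 difference between TNF transgenic and FVB hearts of 3 weeks (x axis) for each measured gene of the 30 tested lists (y axis, with the number of genes), coloured by whether the gene passed an adjusted p of 0.05. Black bars are list medians, from 2.65 for macrophage markers down to -1.12 for fatty acid oxidation and uptake.

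Within females (3 transgenic and 2 FVB arrays), the largest rises were in Mmp12 (6.98), Tnf (6.75), Chil1 (at least 46.1-fold), Ccl2 (5.52) and Cd53 (5.46), and the largest falls in Ces1d (-3.60), Cryl1 (-2.72, with another probe set called in the opposite direction), Ctrb1 (-2.64), Aqp1 (-2.31) and Hand1 (-2.24). Within males (3 arrays each), Tnf was at least 233-fold higher, Chil1 at least 59.3-fold and Mmp9 at least 58.7-fold, since all 3 FVB male arrays lay at the floor. Mmp12 and Ccl2 rose by 6.68 and 5.94, while Aqp1 (-4.31), Adh1 (-3.49), Kcnd2 (-3.16) and Entpd5 (-3.11) fell, and Ces1d, at the floor on all 3 transgenic male arrays, was at least 16.5-fold lower. Macrophage markers rose in both sexes, with 29 of 35 genes higher in females (median 2.47, camera adjusted p = 2.3e-17) and 28 in males (median 2.33, camera adjusted p = 2.0e-21). T and NK markers had 7 of 17 genes higher in females (median 0.87, camera adjusted p = 0.0057, adjusted p = 0.234 with an estimated correlation) and 15 in males (median 2.53, camera adjusted p = 1.4e-08). Camera called 16 lists in females and 19 in males, of which 4 and 8 held with an estimated correlation. Limma called 2587 probe sets in females (1446 higher, 1141 lower) and 2211 in males (1257 higher, 954 lower). The female count was 1446 without the outlying FVB array, 699 with array weights (563 higher, 136 lower) and 1013 with only the groups compared (704 higher, 309 lower). The male count was 1399 (892 higher, 507 lower) without the arrays labelled FVB male 1 and 2, which leaves 1 FVB male array, assumed to vary like the other groups. Scaling arrays to a common median moved the share of higher calls from 55.9% to 68.9% in females and from 56.9% to 40.4% in males.

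The transgene effect itself was compared between the sexes by a contrast of its own. Limma called 0 probe sets, with 1228 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0654. Quantile normalisation gave 6 calls, a common median 17 and no filter 91. Camera called 7 lists, among them T and NK markers, whose effect was lower in females by a median of -1.28 (adjusted p = 4.9e-05, adjusted p = 0.513 with an estimated correlation), and fry called 0. The count was 1490 without FVB female replicate 3, when the outlying array stood alone for its group, and 5 without FVB male replicate 3. Leaving out the outlying array gave 0.

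Between arrays labelled FVB female and FVB male, neither Xist (1.49, SE 1.07, adjusted p = 0.419) nor Eif2s3y (-1.63, SE 0.57, adjusted p = 0.135) was among the called genes. The genes called higher in females were led by Tradd, an adaptor of TNF receptors (2.57), Plxna1 (2.24), Igha (at least 4.3-fold), the potassium channel gene Kcnj11 (1.91) and Zfp472 (1.66). Those called lower were led by H2-K2 (-2.03), Ctla2b (-1.91), Cd53 (-1.65), the transcription factor Klf2 (-1.64) and Rrm1, a subunit of ribonucleotide reductase (-1.54). Limma called 78 probe sets, 38 higher and 40 lower in females. Camera called 5 lists, namely collagen (median -0.35), endothelial (-0.49), T and NK (0.65), B cell (0.45) and neutrophil markers (0.78), all at adjusted p = 0.777 with an estimated correlation. Without the outlying female array the count was 4, with 0 higher and 4 lower, so none of the genes named as higher passed. It was 0 with array weights and with only the groups compared, 2081 without female replicate 3, 14 without male replicate 1 and 8 without male replicate 2. Scaling moved the share of higher calls from 48.7% to 26.7% (quantile) or 17.6% (common median).

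Between transgenic females and males of 3 weeks, the sex-linked genes led. Xist was at least 54.6-fold higher in females, with all 3 male arrays at the floor, and Eif2s3y was at least 10.2-fold higher in males, with all 3 female arrays at the floor. Gsta4, a glutathione transferase, was higher in females by 1.28 (SE 0.21) and Art1, an ADP-ribosyltransferase of muscle, by 1.17 (SE 0.21), while Incenp, of the chromosomal passenger complex, was at -0.88 (SE 0.15). Fatty acid oxidation genes lay higher in females as a list, with a median of 0.49 over 26 genes and none called singly (6 adjusted over the list alone, camera adjusted p = 1.7e-14, adjusted p = 0.0655 with an estimated correlation). Interferon response genes lay lower, with a median of -0.53 over 24 genes (0 called, 1 adjusted over the list alone, camera adjusted p = 2.8e-08, adjusted p = 0.124 with an estimated correlation). Limma called 6 probe sets, 3 in each direction, and camera 13 lists, of which 0 held with an estimated correlation and 3 were called by fry. Leaving out single arrays gave 0 to 2 calls, and quantile normalisation gave 2 calls, both lower in females.

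From 3 to 13 weeks, transgenic male hearts gained immunoglobulin transcripts. Igha, the heavy chain constant region of IgA, rose from 113 ± 6.75 (SD, n = 3) to 3800 ± 325 (SD, n = 3), a log2 difference of 5.07 (SE 0.36, limma adjusted p = 6.9e-07). Jchain, which joins IgA and IgM into polymers, rose by 2.79 (SE 0.39), and the kappa variable genes Igkv6-23, Igkv4-70, Igkv4-68 and Igkv14-111 rose by 3.67, 2.46, 2.40 and 2.13. Igkv9-120, at the floor on all 3 male arrays of 3 weeks, was at least 6.25-fold higher. Outside the immunoglobulins, Gpx3, a secreted glutathione peroxidase, rose by 1.97 (SE 0.24), Mal, a membrane raft protein, by 1.83 (SE 0.29), and Ces1d, at the floor on the same 3 arrays, was at least 4.79-fold higher.

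Fewer genes fell. Gzmb, the granzyme of killer lymphocytes, fell by 2.59 (SE 0.44), the interferon-induced GTPase genes Igtp, Iigp1 and Irgm2 fell by 2.05, fell by 1.87 and fell by 1.55, and the chemokine genes Ccl5 and Cxcl9 fell by 1.75 and fell by 1.46. The rest of the 10 lowest under the naming rule were Casq1, the calsequestrin of fast skeletal muscle (-1.66), Madcam1 (-1.50), Kcne1, a potassium channel subunit (-1.47), and Chil1 (-1.18). Tnf stayed at 8692 ± 1865 (SD, n = 3) against 10418 ± 289 (SD, n = 3), a difference of -0.28 (SE 0.31, adjusted p = 0.921). Nppa (0.57), Nppb (0.41), Myh6 (0.12), Myh7 (0.46), Acta1 (0.39), Atp2a2 (0.52), Col1a1 (-0.40), Col3a1 (-0.75), Timp1 (-0.52) and the Ighm probe set of highest signal (0.09) did not pass.

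Camera called 15 lists for this change, 8 up and 7 down, and 0 held with an estimated correlation. Interferon response genes had 2 of 24 lower (5 adjusted over the list alone, median -0.44, camera adjusted p = 3.1e-07, adjusted p = 0.191 with an estimated correlation). T and NK markers had 2 of 17 lower (4 adjusted over the list alone, median -0.49, camera adjusted p = 3.8e-06, adjusted p = 0.20 with an estimated correlation), and class I genes had 0 of 14 called (6 lower adjusted over the list alone, median -0.43, camera adjusted p = 1.2e-05, adjusted p = 0.191 with an estimated correlation). Chemokines (0 higher, 3 lower of 28, 1 and 3 adjusted over the list alone, median -0.17), cell cycle (0 of 48 called, median -0.24), macrophage (0 of 35, median -0.24) and collagen genes (0 of 37, median -0.18) were the others lower, at estimated-correlation adjusted p = 0.339, 0.459, 0.37 and 0.37. Lists lying higher were oxidative phosphorylation (1 of 53 higher, Cox8b at 1.08, median 0.20, camera adjusted p = 5.4e-06, adjusted p = 0.459 with an estimated correlation) and fatty acid oxidation (0 of 26 called, 2 adjusted over the list alone, median 0.39, camera adjusted p = 2.4e-05, adjusted p = 0.261 with an estimated correlation). Glycolysis (median 0.20), sarcomere (0.23), fetal and hypertrophy (0.36), oxidative stress (0.13), B cell (0.08) and adipocyte genes (0.31) also lay higher, with adjusted p = 0.20 to 0.46 with an estimated correlation. Of their genes Gpx3, Gpx4, Gsta4, Igha and Jchain rose. Fry called 3 lists.

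Limma called 39 probe sets, 26 higher and 13 lower. Each array left out lowered this count, to 14 to 26, and it was 61 with the floor at the 40th percentile and 80 with array weights. There were no FVB hearts of 13 weeks to set beside them, so age and progression with the transgene cannot be told apart.

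From 3 to 40 weeks, transgenic female hearts also gained immunoglobulin transcripts. Igha rose from 51.3 ± 50.2 (SD, n = 3, 2 of 3 arrays at the floor) to 6853 ± 2606 (SD, n = 3), a log2 difference of 6.74 or more (SE 0.36, limma adjusted p = 1.9e-08), and Jchain rose by 3.74 (SE 0.39). The variable genes Igkv6-23, Igkv4-70, Igkv4-91 and Igkv14-111 rose by 5.16, 3.45, 3.19 and 2.91. Igkv4-68, Igkv9-120 and Ighv1-54 rose by 2.73, 2.71 and 2.22, and Cpxm2, a carboxypeptidase-like protein, by 3.25 (SE 0.56). Gpx3 rose by 1.89 (SE 0.24). Aqp4, a water channel, fell by 2.81 (SE 0.46), Casq1 fell by 2.14 (SE 0.27), and Irs2, an adaptor of insulin signalling, fell by 2.02 (SE 0.42). The stress-induced transcription factors Atf3 and Nr4a1 fell by 1.95 and fell by 1.72, haptoglobin, Hp, fell by 1.59, coagulation factor F10 fell by 1.57, and Mlf1 (-1.67), Kcne1 (-1.40) and Fpr2 (-1.33) also fell.

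Acta2, smooth muscle actin, fell by 0.93 (SE 0.19, adjusted p = 0.0337). Tnf was at 10264 ± 1678 (SD, n = 3) against 8390 ± 2934 (SD, n = 3), a difference of 0.34 (SE 0.31, adjusted p = 0.838). Nppa (0.79), Nppb (0.36), Myh6 (0.27), Myh7 (0.91), Acta1 (-0.22), Atp2a2 (0.18), Col1a1 (-0.57), Col3a1 (-0.81), Timp1 (-0.01) and the Ighm probe set of highest signal (1.52) did not pass. Of the 30 lists camera called 2. B cell and immunoglobulin genes had 2 of 20 higher (3 adjusted over the list alone, median 0.27, camera adjusted p = 3.5e-04, adjusted p = 0.366 with an estimated correlation), and immediate early genes had 2 of 19 lower (median -0.18, camera adjusted p = 0.0085, adjusted p = 0.366 with an estimated correlation). Igha and Jchain are the B cell list's 2 called genes, both of antibody secretion. Limma called 50 probe sets, 28 higher and 22 lower. Without female replicate 2 or 3 of 40 weeks the count was 28 or 30, and without female replicate 1 or 3 of 3 weeks it was 31. It was 803 with array weights, 78 with the higher floor and 77 without the filter, and there were no FVB hearts of 40 weeks. The Actb ratio was 1.59, 1.39 and 1.77 on the arrays of 40 weeks and 1.25, 1.44 and 1.28 on the female arrays of 3 weeks, and replicate 3 of 40 weeks had the highest Gapdh ratio (1.52) and 18S signal (33840) of all arrays.

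**Figure D4:**
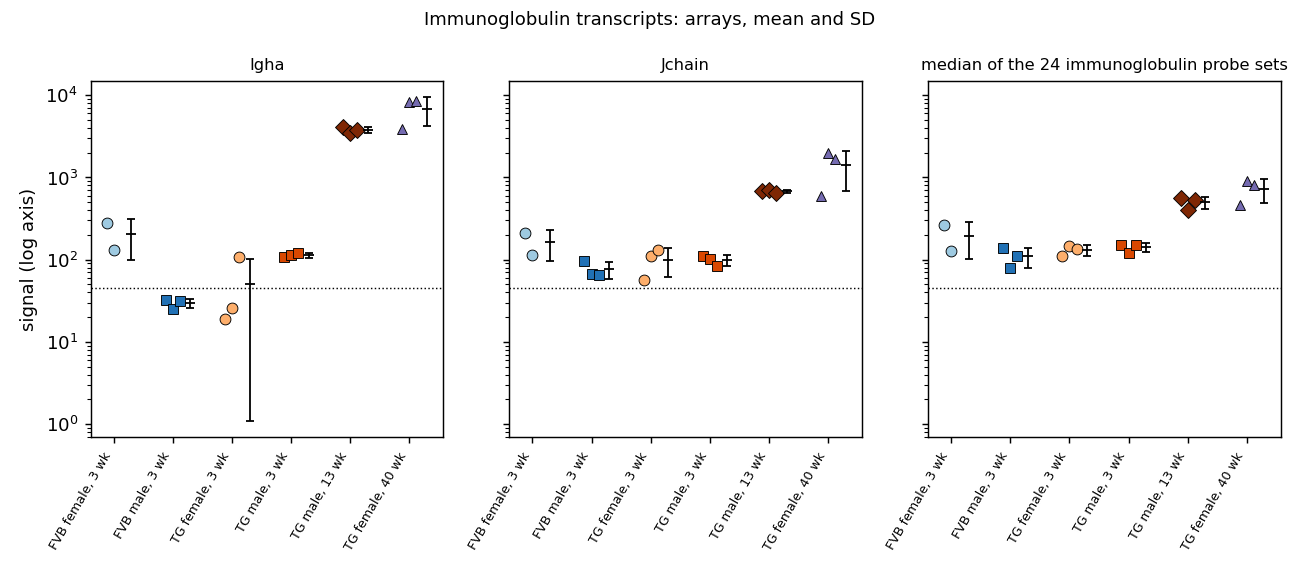
Signal (log axis) of Igha, of Jchain and of the median of the 24 tested immunoglobulin probe sets in each array, by group, with the group mean and SD in black and a dotted line at the floor of 44.675. Igha lies at 3474 to 4123 on the arrays of 13 weeks and at 3848 to 8492 on those of 40 weeks, against at most 283 on any array of 3 weeks.

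The 2 age changes, which share no array, had 20 called probe sets in common. Of these, 16 lay higher in both, 4 lay lower in both and 0 were called in opposite directions. Of the 16, 12 are immunoglobulin probe sets or probe sets without a single gene, and immunoglobulin probe sets share sequence, so they are not independent of each other. Outside the immunoglobulins, the named shared genes were Gpx3, Ces1d, Mal and Aox1, an aldehyde oxidase, higher (Aox1 by 1.39 and 2.09), and Chil1, Kcne1 and Casq1 lower. Aox1 was chosen after its values were seen, as was a second Ighm probe set, which lay at the floor on all 6 transgenic arrays of 3 weeks and was at least 33.8-fold higher at 13 weeks and at least 50.7-fold at 40 weeks. Across the 7453 probe sets, the 2 changes correlated at r = 0.54 and rho = 0.39 and had the same sign in 64.4%; this is across probe sets, which are not independent replicates. The difference between the 2 changes had 0 calls by limma, with 214 probe sets at an unadjusted p under 0.05 and a lowest adjusted p of 0.9997. Camera called 13 lists for it, led by fatty acid oxidation (median -0.52, adjusted p = 8.1e-11, adjusted p = 0.0921 with an estimated correlation) and T and NK markers (0.57, adjusted p = 5.4e-08, adjusted p = 0.103 with an estimated correlation), and 0 held with an estimated correlation or by fry. The contrast also takes in, with opposite sign, the sex difference of transgenic hearts at 3 weeks, where fatty acid oxidation genes lay higher in females. Sex and age differ together between the groups of 13 and 40 weeks and cannot be told apart.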

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

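The test of RNA quality by the Actb ratio was set out before its result was seen. The other tests below, the counts over other splits of the arrays included, were chosen after the result was seen.

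The effect of the transgene at 3 weeks was tested for a difference between the sexes, and camera called it in 7 lists. The median difference, female minus male effect, was 0.38 for collagen and matrix, 0.44 for fatty acid oxidation, 0.35 for oxidative phosphorylation, -1.28 for T and NK markers, -0.41 for B cell genes, -0.79 for neutrophil and mast cell markers and -0.34 for chemokines. Of single genes, limma called 0, with 1228 probe sets at an unadjusted p under 0.05, and T and NK genes had 1 higher and 7 lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.513 to 0.749, and fry called 0. The difference rests on FVB groups with 1 outlying array and 2 arrays whose sex-linked genes go against the label.

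The change from 3 to 40 weeks in females minus the change from 3 to 13 weeks in males differed in 13 lists by camera. The medians were -0.33 for calcium handling, -0.52 for fatty acid oxidation, -0.34 for oxidative phosphorylation, -0.15 for glycolysis, 0.56 for class I and 0.33 for class II presentation, 0.57 for T and NK markers, 0.10 for B cell genes, 0.10 for chemokines, 0.61 for the interferon response, 0.23 for cell cycle, -0.11 for oxidative stress and -0.21 for immediate early genes. Limma called 0 single genes, with 214 probe sets at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.0921 to 0.511, and fry called 0. This contrast takes in, with opposite sign, the sex difference of transgenic hearts at 3 weeks. There, fatty acid oxidation lay higher and the interferon response lower in females, the reverse of their directions here. A difference already present at 3 weeks thus cannot be told apart from changes that differ with age. When ages were permuted within each sex, all 100 of 100 arrangements gave as many calls as the real one. Its count was 0, so this outcome was fixed in advance and says nothing about chance. The highest other gave 168.

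The 66 control probe sets left out of the tests were each looked up in every transgenic group. Some lay above every FVB array on every array of a transgenic group. With so many looks some would do so by chance, and the share expected was not computed. Group means of those that did are given here. The 5' Actb probe set was at 20994 ± 2504 (SD, n = 3) in transgenic males of 3 weeks, 20558 ± 3074 (SD, n = 3) in males of 13 weeks and 18006 ± 801 (SD, n = 3) in females of 40 weeks, against an FVB maximum of 16998. The middle Actb probe set was at 21993 ± 2461 (SD, n = 3) in females of 40 weeks against 19048, the murine FAS probe set at 412 ± 76.4 (SD, n = 3) in males of 3 weeks against 312, and the murine B1 repeat probe set at 11442 ± 1619 (SD, n = 3) in females of 40 weeks against 10130. The 5' Actb signal is the lower term of the Actb ratio given above, so it is not a separate result. No explanation was tested for these probe sets.

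Of the tested probe sets, 46.6% differed between transgenic and FVB hearts at 3 weeks. A fit of the 2 groups without sex gave 2759 calls, and 1 of 100 splits of the 11 arrays, the real one, gave as many. The highest other gave 1268, so no other split tried reached the real count. This makes chance unlikely but does not exclude it. Without the outlying FVB female array there were 3042 calls, 2691 of them shared in direction with the 3474, which argues against that array as the whole cause. The median of macrophage markers exceeded that of endothelial markers by 2.71 (95% interval 1.55 to 3.47, 10000 resamples of 35 and 20 genes, not of arrays). The other cell types thus did not rise alike, as a lower share of cardiomyocytes alone would have them. A gain of macrophages could itself lower that share, so it cannot be told apart as a source of the falls in muscle and metabolic genes. With the Actb ratio as a covariate 42.0% of 3190 calls stayed. Their median absolute log2 difference went from 0.84 (SD 0.71) to 0.73 (SD 0.88) and the median SE from 0.18 to 0.28, and 96.7% had the same sign, so much of the loss goes with the larger SE. Because the ratio differs between the groups, RNA quality cannot be told apart from the transgene as a part of the difference.

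The sex-linked genes of the arrays labelled FVB male 1 and 2 go against the label. A swap with either of the 2 distinct FVB female arrays would leave a female array with Xist at the floor, and 0 were found, which argues against it. A swap with an array outside these files was not tested. FVB male 2 had Xist of 2706, within the transgenic female range of 1721 to 3934, and Eif2s3y of 67.4, so female RNA under a wrong label is a candidate explanation. FVB male 1 had Eif2s3y of 298.7, between the highest array labelled female (115.3) and the lowest transgenic male (347.8), with Xist of 1381, so RNA of both sexes is a candidate explanation for it. No biological explanation was tested.

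Immunoglobulin transcripts rose with age in transgenic hearts: of 24 tested probe sets, 11 rose in males of 13 weeks and 17 in females of 40 weeks, with medians of 1.88 and 2.82 and none lower. These probe sets share sequence, and were counted together after their values were seen. The filter on mean signal over all arrays favours probe sets that are high at the later ages, so these shares and medians partly follow from it. Without the filter, 9 of 70 immunoglobulin probe sets were called higher at 13 weeks and 27 of 70 at 40 weeks, with 0 lower. There were 0 FVB arrays older than 3 weeks, so normal ageing cannot be told apart from the transgene. Lymphoid tissue carried over at dissection would also bring T cells, and T and NK markers had a median of 0.12 (95% interval -0.13 to 0.33, 17 genes) in the females of 40 weeks and -0.49 (95% interval -1.03 to -0.19) in the males of 13 weeks. Their signal at 3 weeks was higher (256 against 133 for immunoglobulins in females, 415 against 143 in males), which could hide a small share, so this too cannot be told apart. Plasma cells in the heart are a biological explanation that stays open and was not tested.

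For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Each time 1 of the 10, the real one, gave as many calls: 2291 for the transgene in males (highest other 0), 3 for transgenic females against males (highest other 2), 57 for 13 weeks (highest other 1) and 40 for 40 weeks (highest other 1).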

How the results depend on the processing

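The transgene effect at 3 weeks gave 3474 calls, and 2447 to 3934 under all alternatives named above, within 1.5 times throughout. The 3934, without the filter, were out of 12422 probe sets. The fit with the Actb ratio as a covariate, not among those alternatives, gave 1617 calls against 3190 without the ratio. Single genes were followed for the most changed genes and the fixed set, not for the examples from lists. Of the 29 such genes called, 699 of 720 gene and alternative pairs kept direction and threshold and 21 only direction. For 13 weeks these were 280 and 70 of 350, for 40 weeks 300 and 49 of 349, and 0 reversed. Most of these genes were picked as large called differences whose groups of arrays do not overlap. The lack of reversals was thus nearly fixed in advance and says little about stability.

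Other counts moved by over 1.5 times, in the order given. Quantile normalisation: sex difference of the effect 6, FVB females against males 146, transgenic females against males 2, lists at 40 weeks 4. A common median: sex difference 17, FVB sexes 216. Floor at the 40th percentile: sex difference 3, transgenic sexes 12, 13 weeks 61, 40 weeks 78. Log2 of signal plus 50: FVB sexes 48, transgenic sexes 11. No filter: sex difference 91, FVB sexes 312, transgenic sexes 2, 40 weeks 77, immunoglobulin probe sets at 40 weeks 27. Brightest 40%: FVB sexes 47, transgenic sexes 3, 40 weeks 30. Trend and robust variance: transgenic sexes 11. Array weights: females 699, FVB sexes 0, transgenic sexes 23, 13 weeks 80, 40 weeks 803, difference of age changes 1. Only the groups compared: females 1013, FVB sexes 0, transgenic sexes 3. Mean over a gene's probe sets: FVB sexes 28. Lists with an estimated correlation: 7, 0 and 0 for the effect, 13 and 40 weeks; with fry 3 and 1 for the age changes. Some list calls of camera changed as well. At 3 weeks, quantile normalisation ended those of adipocyte (adjusted p = 0.0557) and erythroid genes (0.0507) and called B cell genes (0.0413). At 13 weeks it ended those of B cell genes (0.060) and chemokines (0.0532), and at 40 weeks it called fatty acid oxidation (0.0476) and oxidative phosphorylation (0.0076). Some lists stayed called at 3 weeks with smaller medians under quantile normalisation. Sarcomere genes went from -0.88 to -0.45, oxidative phosphorylation from -0.85 to -0.63 and glycolysis from -0.59 to -0.41. Fatty acid oxidation moved less, from -1.12 to -1.06. Fewer probe sets are tested under the brighter filter; otherwise the cause was not tested.

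Added after seeing the data, both identical columns kept gave 174 for the sex difference, 1497 for FVB sexes and 14 for transgenic sexes, since identical columns understate the spread. FVB males 1 and 2 left out gave 1399 in males, 2 for the sex difference and 13 for FVB sexes. Leaving out the outlying array as well gave 1361 in females and 17 for FVB sexes, called cell death genes (camera adjusted p = 0.0414) and ended the call of immediate early genes (0.0615).

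Leaving out 1 array gave 3032 to 3814 calls for the effect, 1446 to 3083 in females (1446 without FVB female 1), 1643 to 1920 in males, 0 to 1490 for the sex difference (1490 without FVB female 3, 5 without FVB male 3, 1 without transgenic female 3), 4 to 2081 for FVB sexes (4 and 2081 without females 1 and 3, 14 and 8 without males 1 and 2), 0 to 2 for transgenic sexes, 14 to 26 for 13 weeks (17, 14 and 14 without 13-week males 1, 2 and 3; 23 and 15 without 3-week males 1 and 2), 28 to 57 for 40 weeks (31 without 3-week female 1 or 3, 28 and 30 without 40-week females 2 and 3) and 0 for the difference of age changes. A lone FVB array, female or male, here and above was assumed to vary like the other groups.

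Signs reversed only for genes not called, while most called genes were picked in a way that makes a reversal unlikely. The cause of the reversals was not tested. By quantile normalisation they were Myh6 (-0.011 at 13 and -0.10 at 40 weeks) and Timp1 (0.0051 at 40 weeks), and by array weights Nppb (-0.030 at 40 weeks). Without FVB female 1 Col3a1 was at -0.11 at 3 weeks, and at -0.028 without FVB males 1 and 2 as well. The others were Ighm at 13 weeks without 13-week male 1 (-0.022) or 3-week male 2 (-0.0002), and at 40 weeks Atp2a2 without 3-week female 1 (-0.039) or 40-week female 1 (-0.10), Timp1 without 3-week female 2 (0.22) or 40-week female 2 (0.19), and Acta1 without 40-week female 2 (0.27). Over all arrays left out, Col3a1 at 3 weeks was -0.11 to 0.73, and at 40 weeks Atp2a2 was -0.10 to 0.42, Timp1 -0.23 to 0.22 and Acta1 -0.86 to 0.27.

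A common median shifted the median of all probe sets by 0.17 in females, -0.19 in males, 0.35 for the sex difference, -0.24 for FVB sexes and 0.11 for transgenic sexes, and quantile normalisation shifted the sex difference by 0.10. With the replicate number as a block, FVB sexes had 2 calls and B cell genes at 3 weeks were called (camera adjusted p = 0.0432). Same-numbered arrays of different groups deviated together at a correlation over 0.1 in 14 of 30 pairs, and other pairs in 16 of 60. The medians were 0.092 and 0.010, so a pairing of the samples by number is neither shown nor excluded. Between males of 13 and females of 40 weeks the 3 values were 0.160, 0.325 and 0.466. A shared deviation of these 2 groups therefore stays open. The floor limits weak genes, whose differences are compressed.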

Other observations

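Both tests here were chosen after the result was seen. Interferon and T and NK genes lay higher with the transgene at 3 weeks and lower at 13 weeks as lists. With an estimated correlation the 13-week calls were lost (adjusted p = 0.191 and 0.20), as was that of T and NK genes at 3 weeks (0.10), and 2 of 24 and 2 of 17 genes passed at 13 weeks. This raised the hypothesis that transgenic hearts may return towards FVB levels. To avoid shared arrays, each age change was correlated with the transgene effect of the other sex. For males of 13 weeks r was -0.41 across probe sets, which are not independent replicates, with opposite signs in 77.7% of the 2587 probe sets called in females, but another of the 10 splits of the arrays reached 0.46 in size. For females of 40 weeks r was -0.046, with opposite signs in 53.4% of the 2211 probe sets called in males, and another split reached 0.32. Neither test bore the hypothesis out, but 10 splits are too few for a share under 0.05, so it is not refuted either. Both tests ran over all tested probe sets, and not over the interferon and T and NK genes alone.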
